A study of Drosophila melanogaster with 6 samples.

How the data were processed

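ChIP-seq was done on flight muscles of pharate Drosophila melanogaster, 96 h after pupa formation, with chromatin fixed in 1.8% formaldehyde, per the labels' protocols. Mouse antibodies against Rbf were used in 2 samples and a rabbit antibody against Dp in 2 samples, and 2 input samples had no antibody. The growth protocol gives 25 °C for all the samples, while the stage label of the Dp samples reads 5 °C. Which of these holds for the Dp samples is not settled by the labels.

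The submitters' processing notes name bcl2fastq 1.8.3, Bowtie2 2 and MACS 1.4.2, and the genome build BDGP5, without saying what each was used for. The deposited values used here were 2 peak lists, 1 for each antibody, with 5 columns and no header. Column 5 is a score that the authors' peak calling gave each peak, and its unit is not given in the sources used here. No score was below 50.01 in either list, and scores piled up at 3100, which limits ranking among the highest peaks. Each list covers both samples of its antibody, and whether reads were pooled or separate calls merged is not stated. Whether the input was the control in peak calling is not stated either. Read depth per sample is unknown, so a list with more peaks may come from a deeper or more enriched sample, and counts of peaks were not read as amounts of binding. No file of a single sample and no input signal was used here, and no values per replicate could be compared.

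Positions are printed 1-based in the deposited coordinates. Peaks were called shared when they had at least 1 bp in common, and counts of shared peaks were checked against bedtools 2.31.1. Shares have exact Clopper-Pearson intervals at 95%. As a reference for each share, the Dp list was shifted in a circle by a random offset on each arm 100000 times (10000 for each alternative). Shifts keep the spacing of peaks but not a preference for promoters that both lists may have. The largest peak end in both lists stood for the length of an arm. Median scores of shared and other peaks were compared by a two-sided permutation test with 100000 resamples. Counts in 2 classes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 5 tests of X against the large autosome arms. Ratios of densities have intervals from the counts of peaks. The mitochondrial genome was kept in the overlap and left out of densities. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

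On simulated lists of 3470 Rbf peaks, planted overlaps of 19.9%, 49.9% and 80.0% were recovered as 19.9%, 49.9% and 80.0%. Of 100 copies of the Rbf list rotated by a random amount on each arm, 5 had p under 0.05. The score test, run on shuffled Rbf scores, called 20 of 20 simulations with 1.5-fold higher scores and 2 of 20 with no difference. Planted peaks were centred on Dp peaks, and rotating and shuffling are what the tests themselves do. These checks therefore cover the code only. They cannot show how the overlap test behaves when unrelated lists prefer the same kind of site.

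The tests of overlap and of overlap by score, their alternatives and the rule for named peaks were fixed before the data were examined. The rule names the 10 peaks of highest score in each list, with ties broken by genomic position, and any other region is said to have been chosen after its values were seen. The comparisons of X with autosome arms and of centromere-proximal stretches, and the limits of 300 bp and 2 Mb, were added after the data were seen. Other settings fixed beforehand for the overlap were 50% of each peak, 500 bp of distance, 200 bp midpoint windows, peaks above the median score, a score of at least 100, the 6 arms alone, equal numbers of peaks and 1000 random placements. Settings added later were shifts of 20 to 200 kb, leaving out X, leaving out chromosomes 4 and M with proximal stretches, leaving out narrow Rbf peaks, and counting peaks at most 5 kb apart once.

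The gene annotation at hand belongs to Release 6 of the genome, another build, and coordinates were not converted. Peaks were therefore not assigned to genes, and the planned tests of promoters, bound genes, 15 gene lists and sequence motifs were not run. The planned test of peak counts against arm length was not run either, since no chromosome lengths of the same build were used.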

Results

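Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Rbf and Dp sit on the genome of Drosophila flight muscles. Rbf is a fly member of the retinoblastoma family, which represses transcription mainly by binding E2F factors. Dp is the partner with which E2F factors bind DNA. Muscles came from pharate animals, the stage just before the adult ecloses, about 96 h after pupa formation. The animals carried an RNAi construct against mCherry, a fluorescent protein that flies do not have, under the muscle driver Mef2-GAL4, and served as wild type. The 6 samples were 2 Rbf ChIPs, 2 Dp ChIPs and 2 inputs of chromatin without immunoprecipitation. The series text describes the 2 samples per antibody as independent biological samples. The values analysed were 1 peak list for each antibody, so no replicate spread could be computed and the depth of each sample is unknown. Intervals below are 95% intervals that cover counting error over peaks only. Neighbouring peaks are not independent, so these intervals are narrower than replicate error would make them.

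The Rbf list held 3471 peaks and the Dp list 5149. Dp peaks were wider, with a median of 905 bp (quartiles 607 and 1333) against 528 bp (345 and 746) for Rbf. On the 6 chromosome arms, Dp peaks covered 7574 kb, or 6.30% of the span that the lists reach, and Rbf peaks covered 2650 kb, or 2.20%. Peaks under 300 bp made up 17.3% of the Rbf list (601 peaks) and 0.0971% of the Dp list (5 peaks). Peaks of at least 4 kb held 39.1% of the covered length in the Dp list (488 peaks) and 15% in the Rbf list (71 peaks). The authors' score of a peak had a median of 354.21 in the Dp list and 147.96 in the Rbf list, and it ranks peaks only within its own list. Many of the highest scores were tied at 3100, with 13 Rbf and 76 Dp peaks at exactly that value.

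The highest Rbf score, 3205.34, belonged to a 945 bp peak on arm 2L at 16487361 to 16488305, in coordinates of build BDGP5. It lay inside a Dp peak at 16487260 to 16488497. Of the 10 Rbf peaks named by the rule, 9 overlapped a Dp peak, but 9 of the 10 were tied at 3100 and taken by genomic order. Without Dp was an 8360 bp peak on 2R at 2315006 to 2323365. A tied Rbf peak on chromosome 4 at 1282034 to 1293596, which that order left out and which is named after its values were seen, also lacked Dp. The other Rbf peaks of the 10 included a pair of neighbours on 2L at 22408861 to 22412605 and 22412731 to 22416170, and 4 on 3L between 23105535 and 23842856. One more lay on 2R at 750892 to 756556 and another on 3R at 27780910 to 27781463. All 10 Dp peaks of highest score overlapped an Rbf peak. The highest, 3217.88, was at 11424769 to 11425954 on 2R, over an Rbf peak at 11425050 to 11425878. The next were at 2236516 to 2237878 on 3L (3198.75), at 22754427 to 22760029 on 3L (3190.54) and at 8883937 to 8885364 on 3L (3174.70). Another Dp peak of the 10 spanned 9891 bp on 3L at 5107840 to 5117730 and held 4 Rbf peaks. Genes at these positions are not named, because the gene annotation used here belongs to another build.

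Antibodies against Rbf and Dp were used in the same tissue, which lets their binding sites be compared. The Dp samples were registered apart from the Rbf and input samples, and no input was registered with them. Whether the ChIPs were done side by side is not known here. Differences between the lists therefore cannot be told apart from differences between separate experiments. Most Rbf sites were also Dp sites, and a smaller share of Dp sites were also Rbf sites. Of the 3471 Rbf peaks, 2844 (81.9%, exact interval 80.6 to 83.2) shared at least 1 bp with a Dp peak. Of the 5149 Dp peaks, 2361 (45.9%, 44.5 to 47.2) shared at least 1 bp with an Rbf peak. The remainder comprised 627 Rbf peaks (18.1%) and 2788 Dp peaks (54.1%). Both shares exceeded those from shifting the Dp list around each arm, which averaged 9.19% of Rbf peaks and 5.70% of Dp peaks. Observed overlap was 8.92-fold and 8.04-fold above those means. The two-sided permutation p was 1.0e-05 for each, the smallest that 100000 shifts can give. The Rbf share depended on what counted as shared: it was 35.4% when each peak had to cover 50% of the other, and 52.6% between 200 bp windows at the midpoints. The corresponding Dp shares were 23.8% and 35.3%. Among peaks above each list's median score the shares were 81.3% for Rbf and 51.8% for Dp. With the Dp list cut to its 3471 peaks of highest score, so that both lists were equally long, they were 74.4% and 61.4%. The gap between the lists thus narrowed. That cut also drops the Dp peaks of low score, which were seldom shared, so list length and score are not separated. If both peak lists were called against the same input, part of the overlap may come from that input. Shifting also removes any preference for promoters common to both lists, which could by itself raise overlap above the shifts. The planned test within promoters was not run, so the excess over shifts cannot be read as joint binding alone.

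Shared sites had a nested shape, with the Rbf peak inside the Dp peak. On the arms, 2772 of the 2843 shared Rbf peaks (97.5%) lay wholly inside a Dp peak. Dp peaks contained 83.6% of the length covered by Rbf, while Rbf peaks contained 29.3% of the length covered by Dp. The midpoints of overlapping peaks were a median of 110 bp apart (quartiles 43 and 400). Most shared Dp peaks held 1 Rbf peak (2031 peaks), and 329 held 2 or more. The most was 6, in a Dp peak on 3L at 24345842 to 24353594, which is named for that count after it was seen. Shared peaks were also wider than the others, with medians of 559 bp against 279 bp for Rbf and 1072 bp against 671 bp for Dp. Peak width itself raises the chance of overlap, and these widths were not tested.

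Dp peaks of high score were nearly always shared with Rbf, and those of low score seldom were. The share of Dp peaks with an Rbf peak was 11.9% (10.2 to 13.8) in the lowest of 4 equal score classes, then 21.5%, 55.2% and 94.9% (93.5 to 96.0) in the highest. Circular shifts gave 4.06% to 6.94% in these classes. For Rbf the share changed less, from 74.0% (70.9 to 76.9) in the lowest class to 92.6% (90.7 to 94.3) in the highest, against 8.34% to 10.7% in shifts. The median Dp score was 1146.13 in shared and 158.99 in other peaks, a difference of 987. The median Rbf score was 165.65 in shared and 100.63 in other peaks, a difference of 65. Both differences had a two-sided permutation p of 1.0e-05, the smallest that 100000 resamples can give. The Rbf difference rose to 224 with overlap of 50% of each peak, to 127 with midpoint windows and to 103 without chromosomes 4 and M and the centromere-proximal 2 Mb.

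**Figure D1:**
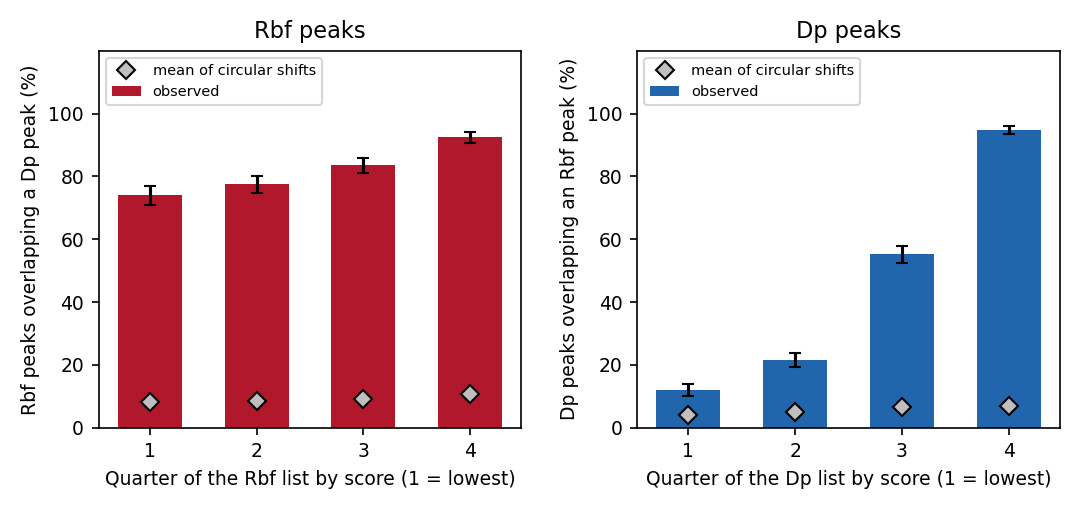
Percentage of Rbf peaks (left) and Dp peaks (right) that overlap a peak of the other list, in 4 classes of their own list by score; bars are observed shares with exact 95% intervals, and diamonds are means of circular shifts. The Dp share runs from 11.9% to 94.9%, and the Rbf share from 74.0% to 92.6%.

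Peaks of both proteins were spread over all the arms, and chromosome 4 had the most Rbf peaks for its length. Rbf density was 51.1 peaks per Mb of listed span on chromosome 4 (39.7 to 64.7), 33.3 on X (31.0 to 35.8) and 27.5 over the large autosome arms 2L, 2R, 3L and 3R (26.5 to 28.6). Of the 69 Rbf peaks on chromosome 4, 22 lay in 1 stretch of 80 kb at its listed end, chosen after its values were seen. Dp density was 48.9 per Mb on chromosome 4 (37.8 to 62.2), 41.9 on X (39.2 to 44.6) and 42.9 over the large autosome arms (41.6 to 44.3). On 2R alone it was 50.5 (47.5 to 53.7), so chromosome 4 did not stand out for Dp. X held 22% of Rbf peaks on X and the large autosome arms, against 18.5% of Dp peaks (odds ratio 1.24, 1.11 to 1.39, Fisher's exact test, two-sided p = 8.0e-05). That ratio turned to 0.922 (Fisher's exact test, p = 0.19) when Rbf peaks under 300 bp were left out. Densities use the largest peak end on each arm as its length, a choice made after the data were seen. The mitochondrial genome carried 1 peak in each list, of 18612 bp for Rbf and 18205 bp for Dp. Both began at position 1, scored 3100 and counted as shared in the overlap. On the 6 arms alone, the overlap was 81.9% of Rbf and 45.8% of Dp peaks.

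Rbf sites without Dp were most frequent on X among the large arms. On X, 474 of 747 Rbf peaks (63.5%, 59.9 to 66.9) overlapped a Dp peak, against 2323 of 2654 (87.5%, 86.2 to 88.8) on the large autosome arms. Single autosome arms ranged from 84.5% on 2L to 89.2% on 2R, and chromosome 4 had 66.7% (54.3 to 77.6). The Dp share differed less, with 41.3% on X and 46.8% on the large autosome arms (odds ratio 1.25, 1.08 to 1.45, Fisher's exact test, adjusted p = 0.0020). For Rbf the odds ratio was 4.04 (3.33 to 4.90, Fisher's exact test, two-sided p = 3.4e-46, Benjamini-Hochberg adjusted over 5 tests 1.7e-45). This comparison was chosen after the data were seen, and its size depended on the setting: 1.53 with overlap of 50% of each peak, 1.66 with midpoint windows and 2.30 without Rbf peaks under 300 bp.

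Narrow Rbf peaks were denser on X than on the autosome arms, and all 5 Dp peaks under 300 bp lay on X too. X carried 263 Rbf peaks under 300 bp, 11.7 per Mb, and the large autosome arms had 3.46 per Mb, a ratio of 3.39 (2.87 to 4.0). Of these, 23.6% (18.6 to 29.2) on X and 50% (44.5 to 55.5) on the autosome arms overlapped a Dp peak, an odds ratio of 3.24 (2.24 to 4.71, Fisher's exact test, adjusted p = 7.5e-11). Among Rbf peaks of at least 300 bp the shares were 85.1% (81.6 to 88.2) on X and 92.9% (91.8 to 93.9) on the autosome arms, with an odds ratio of 2.30 (1.68 to 3.11, Fisher's exact test, adjusted p = 3.2e-07). The intervals of the 2 odds ratios overlap, and their difference was not tested. The narrow X peak of highest score without Dp was at 18790246 to 18790529 (724.82), and the next was at 8862825 to 8863065 (531.11), both named after their values were seen.

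**Figure D2:**
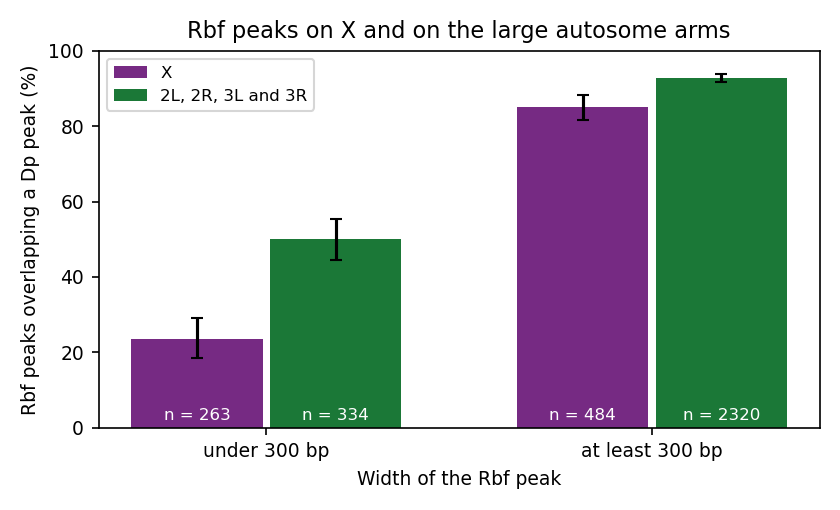
Percentage of Rbf peaks that overlap a Dp peak (vertical axis) for peaks under 300 bp and of at least 300 bp (horizontal axis), on X and on the 4 large autosome arms, with exact 95% intervals and the number of peaks in each bar. The lowest bar is that of narrow peaks on X, at 23.6%, and the highest that of wider peaks on the autosome arms, at 92.9%.

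Both proteins had more peaks near the centromeres of most arms, and Rbf more so. In the 2 Mb of listed span nearest the centromere of X and each large autosome arm, Rbf had 82.0 peaks per Mb against 23.7 elsewhere, a ratio of 3.46 (3.2 to 3.75). Dp had 80 against 39.3, a ratio of 2.04 (1.89 to 2.20). The Rbf ratio was highest on 3L (6.22, 5.32 to 7.26) and lowest on 3R (1.45, 1.11 to 1.88), and the Dp ratio ran from 2.92 on 3L to 1.24 on 3R (0.984 to 1.54). The full 1 Mb bin with the most Rbf peaks was 3L from 23000001 to 24000000 with 146, and that with the most Dp peaks was 2R from 1 to 1000000 with 133, against medians of 22 and 40 per bin. Proximal peaks scored lower in the median, at 94.5 against 178 for Rbf and 177 against 427 for Dp. Some of the highest Rbf scores were proximal all the same. Of the named Rbf peaks tied at 3100, those on 2L, on 3L and at 750892 on 2R lay in these stretches. Those at 2315006 on 2R and on 3R did not. Proximal peaks made up 24.1% of Rbf and 15.7% of Dp peaks on these arms, an odds ratio of 1.70 (1.52 to 1.90, Fisher's exact test, two-sided p = 1.6e-21). Counting peaks at most 5 kb apart once lowered the density ratios to 1.67 for Rbf and 1.32 for Dp. It also lowered the odds ratio between the lists to 1.26 (Fisher's exact test, p = 0.0067). Merging removes the most peaks where they are densest, so part of these falls is built into it. Clustered peaks are also not independent. Using only peaks above each list's median score lowered the density ratios to 1.89 and 1.15 and gave an odds ratio of 1.64. Without Rbf peaks under 300 bp the odds ratio rose to 1.96. This comparison was also chosen after the data were seen.

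**Figure D3:**
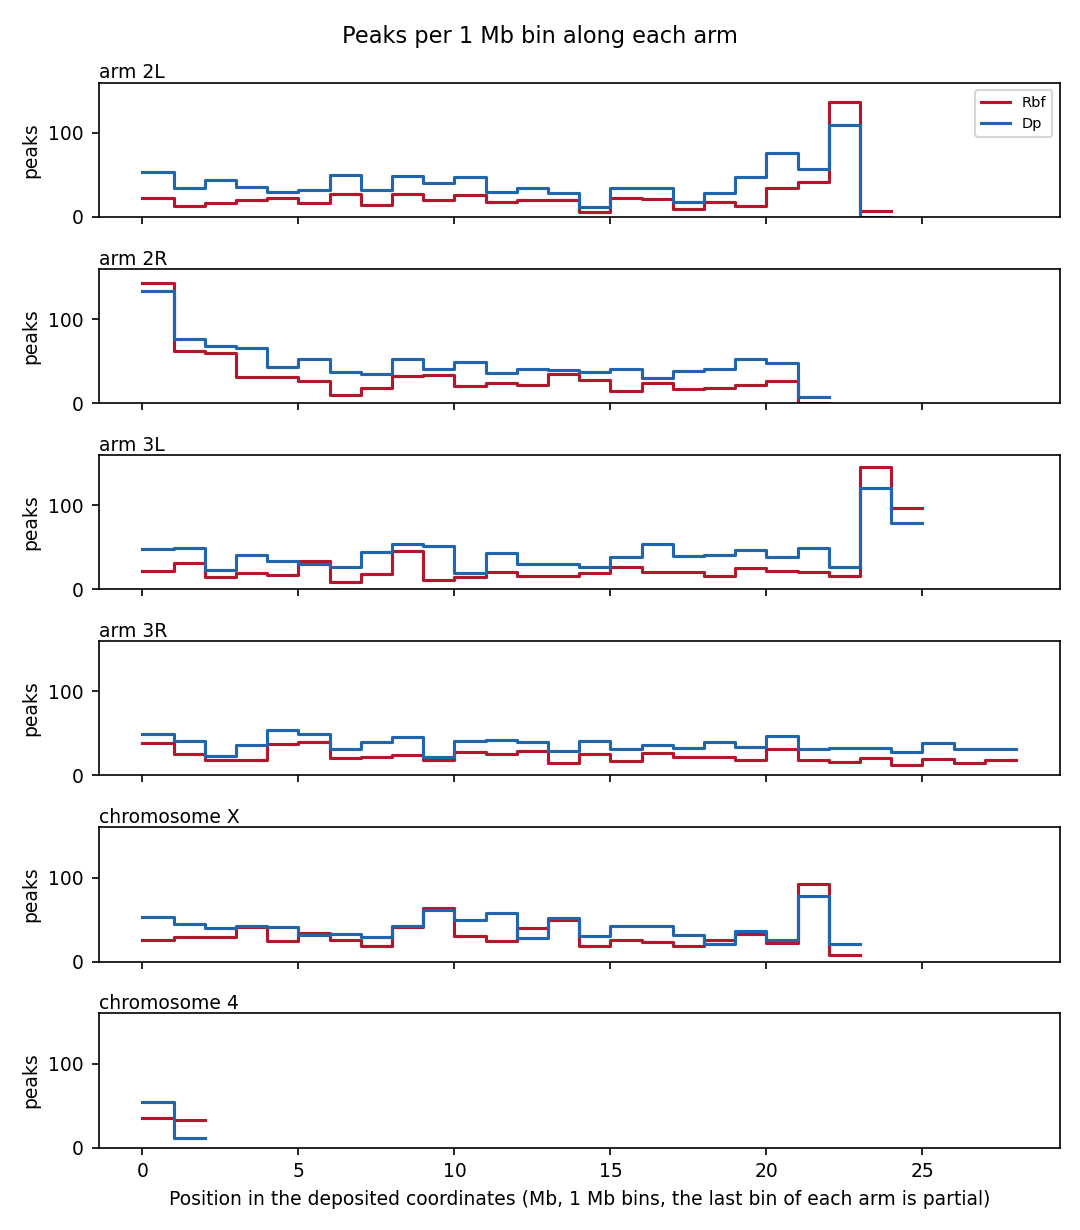
Number of Rbf (red) and Dp (blue) peaks in each 1 Mb bin (vertical axis) along each arm in Mb of the deposited coordinates (horizontal axis); the last bin of each arm is partial. Both lines rise at the right end of 2L and 3L and at the left end of 2R, to 146 Rbf peaks on 3L and 133 Dp peaks on 2R.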

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

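All the tests in this part were chosen after the results were seen. Odds of lying on X rather than on a large autosome arm differed between the lists. Among peaks without a partner in the other list, 273 of the Rbf peaks (45.2%) and 551 of the Dp peaks (20%) were on X, an odds ratio of 3.3 (2.73 to 3.99, Fisher's exact test, p = 2.8e-35), which fell to 1.72 (Fisher's exact test, p = 4.6e-04) without Rbf peaks under 300 bp. Among all peaks the ratio was 1.24, and it fell below 1 to 0.922 without those narrow peaks. The odds of lying in the centromere-proximal 2 Mb also differed, with an Rbf over Dp ratio of 1.70. That ratio was 1.26 with peaks at most 5 kb apart counted once.

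Of the 273 Rbf peaks without Dp on X, 201 were narrower than 300 bp. If Dp peaks were missed on X, wider Rbf peaks there could lack Dp too. Of them, 85.1% (81.6 to 88.2) had a Dp peak against 92.9% on the autosome arms (odds ratio 2.30, 1.68 to 3.11). They thus lacked Dp more often, although most had it. The density of all Dp peaks on X over the autosome arms was 0.975 (0.907 to 1.05), and 1.04 (0.961 to 1.12) without proximal stretches. No general shortage in the number of Dp peaks on X was seen. Dp peaks on X did have a lower median score, 307 against 382 on the large autosome arms. Their median width was also smaller, 807 bp against 929 bp, and neither difference was tested. A loss of Dp peaks at some sites on X stays open. A copy number of X that was higher in the Rbf ChIP than in its control could also add peaks: the density of wider Rbf peaks on X over the autosome arms was 0.899 (0.813 to 0.992) over whole arms, below 1, but 1.02 (0.915 to 1.14) without proximal stretches, which are richer in Rbf peaks on most autosome arms than on X, so this stays open. A further look, split by score and also without proximal stretches, gave 3.11 (2.55 to 3.80) for narrow and 1.17 (0.969 to 1.4) for wider Rbf peaks below the median score, and 7.54 (5.09 to 11.3) and 0.951 (0.824 to 1.09) above it, but no bound that copy number forbids was set in advance. Reads shared between copies of a repeat on X, and binding of Rbf without Dp, were not tested, since no sequence of the build was used, and cannot be told apart here.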

How the results depend on the processing

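Alternatives that were added after the data were seen are the local shifts, the left-out chromosomes, arms and narrow peaks, the merging of neighbours, and those of Rbf overlap on X, of peaks without a partner on X and of centromere-proximal stretches. For the odds of X, itself an added comparison, the restriction to peaks above the median score was fixed beforehand and gave 1.30. Of 70 alternative values for 10 results, 69 kept the direction and the side of the 0.05 threshold. The share of Rbf peaks with a Dp peak ranged from 35.4% to 91.0%, and that of Dp peaks with an Rbf peak from 23.8% to 61.4%, the latter with equal numbers of peaks. Fold over the shifts was lowest with local shifts of 20 to 200 kb, at 6.09 for Rbf and 5.86 for Dp. The difference of median scores ranged from 62.1 to 224 for Rbf and from 984 to 1135 for Dp. The odds ratio of Rbf overlap on autosome arms over X ranged from 1.53 to 5.69, and the proximal density ratio from 1.67 to 4.71 for Rbf and from 1.15 to 2.51 for Dp. Between the lists, the odds ratio of X among peaks without a partner ranged from 1.72 to 4.58, and that of the proximal stretches from 1.26 to 1.96. The 1 value that reversed was the odds of X for Rbf over Dp peaks, from 1.24 to 0.922 (Fisher's exact test, p = 0.19) without Rbf peaks under 300 bp, and the removed peaks were denser on X by 3.39 times. No paired analysis was possible because the lists hold 1 value per peak over both replicates, and for the same reason no replicate could be left out. Of 28 settings fixed beforehand, 17 were not run: those for genes, gene lists and motifs needed an annotation or sequence of the same build, and 1 needed values per replicate. Unknown depth limits every comparison of the number of peaks between the lists.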

Other observations

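All the tests in this part were chosen after the results were seen, and the regions were named after their values were seen. Dp peaks of high score that lacked Rbf were mostly wide. In the highest of the 4 score classes on the arms, 1053 of 1059 Dp peaks under 4 kb (99.4%, 98.8 to 99.8) overlapped an Rbf peak, against 167 of 227 of at least 4 kb (73.6%, 67.3 to 79.2; odds ratio 63.1, 26.6 to 181, Fisher's exact test, p = 1.9e-41). Stretches in which consecutive Dp peaks all lacked Rbf included 20 peaks on 3L at 8961420 to 9353556 and 19 on 3L at 7632370 to 7806870. Consecutive Rbf peaks without Dp included 20 on 2L at 22988467 to 23010932 and 12 on X at 21586727 to 21619926. X also had a stretch rich in shared peaks, from 9000001 to 10000000, where 87.5% of 64 Rbf peaks overlapped a Dp peak.

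Scores of overlapping peaks rose together across peaks, which are not independent replicates. Over 2843 shared Rbf peaks, Pearson's r of the log10 scores was 0.48 and Spearman's rho 0.54 (permutation p = 1.0e-05 for each, adjusted over both coefficients of the 6 sets together 1.1e-05), and both were the same without the 2 farthest peaks. On the large autosome arms r was 0.54 and rho 0.59, and on X 0.20 and 0.26. The difference between X and the autosome arms was not tested.

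On chromosome 4, the stretch with the most consecutive Rbf peaks without Dp lay at the listed end. From 1270715 to 1350667 there were 22 Rbf peaks over 68.9% of 80 kb, with a highest score of 3100, and none overlapped a Dp peak, as the stretch was chosen for that. Elsewhere on the chromosome 46 of 47 Rbf peaks (97.9%) overlapped a Dp peak. A background common to both ChIPs could give Dp peaks there too: the number of Dp peaks was 1 against 4.09 at the rate of the rest of the chromosome, a count too low to decide, and the choice of the stretch itself favours a low one. Reads from repeats enriched only in the Rbf ChIP could give the 22 peaks as well, and these cannot be told apart from binding of Rbf without Dp, since no sequence of the build was used.

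Some wide Dp peaks had similar widths. The fullest class of 250 bp from 3 kb up, chosen for that, was 4750 to 4999 bp, with 77 peaks on 5 arms against 28 and 47 in the neighbouring classes; the Rbf list had 4 peaks of these widths. Of the 10 highest Dp peaks without Rbf, 8 fell in this class, among them 9217946 to 9222779 on 2L (score 2000.78) and 6286880 to 6291713 on X (1922.63). The others were 7693 bp wide on 2L and 7711 bp wide on X. Their class, 7500 to 7749 bp, held 33 Dp peaks against 15 and 12 in its neighbours, which was not tested. For the class of 4750 to 4999 bp, the ratio to the mean of both neighbours was 2.05 (1.22 to 3.45, corrected over 26 classes). The fullest classes of 200 bp and 500 bp gave 2.12 (1.20 to 3.76) and 1.59 (1.08 to 2.33). All of these go against a smooth tail of broad peaks. With the edges of the 250 bp classes moved, the fullest gave 1.49 (0.862 to 2.53), which leaves a smooth tail open. Reads shared between copies of an element of fixed length, such as a transposon, could also give the 77 peaks, which stays open because no sequence of the build was used; no biological explanation was tested.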
